A study of Homo sapiens with 6 samples.

How the data were processed

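RNA from 6 libraries of the line SNU-368, 3 labelled shCtrl and 3 labelled shTFAM, was analysed. Per the labels' protocols, poly(A) RNA was purified from TRIzol extracts, fragmented, and made into dUTP-marked libraries that keep the strand, then sequenced as paired reads on an Illumina NovaSeq instrument. The submitters' processing notes name Bowtie 0.12.2, cutadapt 1.9, HISAT2 2.0.4 and StringTie 1.3.4d, and the builds mm8 and hg38, with no roles. Row coordinates are human and are given here as hg38; which tool made the counts, with which annotation and strand setting, is not given in the sources used here. The authors deposited 1 table of 60612 Ensembl gene rows with 12 value columns, 6 of whole-number counts and 6 of FPKM, which are scaled to gene length and depth, per the file headers. The ratio of counts to FPKM differed between libraries by 1 factor per library over rows of more than 200 counts, with an SD of at most 0.0017 log2 units, so the FPKM follow from the same counts. A row with a count of 0 is given an FPKM of at most 1e-04. Overlapping genes, near-identical copies and antisense pairs can share reads in such a table.

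Groups were taken from the treatment label, and columns were matched to samples by title. Titles give no shared replicate numbers, so no pairing was used and replicates were numbered in accession order. The test fixed before the data were examined was limma on log2(FPKM + 1), because only FPKM were foreseen. As the table holds counts, edgeR's quasi-likelihood test on the deposited counts was used instead, and the limma test was kept as an alternative. The filter stayed as fixed, a mean FPKM of at least 0.5 over the 6 libraries, and left 14708 rows, which held 99.4 to 99.5% of counts. Libraries were scaled with TMM factors from 0.951 to 1.04, dispersions followed the abundance trend, and p-values were two-sided with Benjamini-Hochberg adjustment over all tested rows. The common biological coefficient of variation was 0.251. SE is the log2 fold change divided by the root of the F statistic. CPM are counts scaled by TMM-adjusted library sizes. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and matplotlib 3.10.9.

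Before the data were examined, 33 gene lists with 974 members were fixed, and all members were found in the table. Some genes belong to several lists, such as CCN1 among the targets of SRF and of YAP and TAZ. The 31 lists with at least 5 tested members were tested with limma's camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists. Of these, 21 passed, 14 higher and 7 lower, and 0 passed with an estimated correlation. Limma's fry, also fixed in advance, asks whether a list's members shift, without comparing them with other genes. Of the 21, it did not call mtDNA-encoded mRNAs (fry adjusted p 0.109), complex I (0.238), cytosolic ribosomal proteins (0.125) or endoplasmic reticulum stress (0.373). The other lists that camera called passed fry in the same direction, with fry adjusted p up to 0.0472. Genes are named by a rule also fixed then: TFAM, the 13 mtDNA-encoded mRNAs, 9 genes of the series title and of malonyl-CoA metabolism, the 12 largest rises and 12 largest falls among non-overlapping called rows with a mean of at least 5 FPKM in the higher group and an ordinary symbol, and up to 4 called members per list with the smallest p, or 2 by abundance where none was called. Other genes named in the text were chosen after their values were seen. Terms of the table's Gene Ontology column with 10 to 500 tested genes were tested with camera in the same way. GC content and length came from the longest GENCODE transcript (release 29) of each gene, found for 14603 of the tested rows.

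On simulated counts with the real means and library sizes, with 200 genes and a further raised list of 30 changed in each of 5 runs over 14708 genes, the test recovered 2.76% of genes changed by 0.5 log2 units, 41.1% of those changed by 1 and 83.9% of those changed by 2. It called 0.0539% of unchanged genes, 7.49% of all calls, those of the raised list included. Fewer genes were changed in each run than the 2630 called in the data. Adjustment is then stricter, so the shares recovered do not give the sensitivity in the data. The raised list was called in 5 of 5 runs and a flat list in 0. Genes were simulated independently, so these runs cannot show how the list test behaves where genes vary together. Replicates were compared before averaging: no pair agreed within sampling noise, the lowest chi-square per degree of freedom being 42.2. Alternatives fixed in advance were other filters, other scalings, a pseudocount of 0.1, other variance models, rows summed per symbol, stricter thresholds and each library left out in turn. Those for the pseudocount and quantile normalization act on log2 FPKM and were run with limma, and those for scaling were run in edgeR. Scaling to the counts outside mtDNA used no TMM factors. The limma test on log2(FPKM + 1), fixed before, became an alternative when edgeR took its place. Alternatives chosen after the data were seen were DESeq2, scaling to library totals, edgeR's own filter, and leaving out shCtrl 3 and shTFAM 3 together. No outlier test was made, since groups of 3 are too small for it. Results for some genes that the naming rule takes are not reported here.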

Results

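Gene expression was measured by RNA sequencing in 6 libraries of SNU-368, a human hepatocellular carcinoma line by its labels. Of these, 3 libraries came from cells with a control short hairpin RNA (shCtrl) and 3 from cells with a hairpin against TFAM (shTFAM). TFAM is the mitochondrial transcription factor that packages mitochondrial DNA (mtDNA) and is needed for its transcription. The shCtrl libraries held 43286024, 50910536 and 47868918 counts, and the shTFAM libraries 46539070, 46263488 and 61058282. A floor of 3 counts corresponded to 0.0491 to 0.0693 CPM, counts scaled to library size, across libraries, a limit that covers counting error only. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. The first principal component held 46.0% of the variance and separated the groups, and shCtrl 3 stood apart from the other shCtrl libraries on the second (16.6%).

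The single comparison of the series asked how the transcriptome differs when TFAM is reduced, in a study whose title concerns nuclear actin, the formin mDia2 and metastasis. In shTFAM cells, lists of hypoxia, glycolysis, mesenchymal, epithelial, matrix protease, adhesion and SRF target genes were higher by camera at its preset correlation. Lists of the mitochondrial ribosome, mtDNA maintenance and mitochondrial chaperones were lower by the same test. In all, 21 lists passed, and 0 passed with an estimated correlation. Of 14708 rows tested with edgeR's quasi-likelihood test, 2630 passed an adjusted p of 0.05, 1661 of them higher and 969 lower in shTFAM. Of the 2630, 643 were at least 1 log2 unit higher and 267 at least 1 log2 unit lower. The groups did not overlap in 6209 rows (42.2%, against 10% by chance for 3 against 3). The direction split depended on scaling. Scaling to library totals, without TMM factors, gave 1353 higher and 1272 lower, and moved the median log2 fold change of all rows from -0.015 to -0.090. Scaling to the counts outside mtDNA, also without TMM factors, gave 1198 and 1771 and a median of -0.15. The test on log2(FPKM + 1) gave 1278 and 1337. Leaving out shCtrl 1 gave 1263 rows, shCtrl 2 1148, shTFAM 1 1752, shTFAM 2 1372 and shTFAM 3 1408.

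TFAM itself (ENSG00000108064, chromosome 10, 58385345 to 58399220, plus strand, hg38) was lower in all 3 shTFAM libraries than in any shCtrl library. It stood at 82.7 ± 6.73 CPM in shCtrl (SD, n = 3) and 61.8 ± 4.50 CPM in shTFAM (SD, n = 3). The log2 fold change was -0.42 (SE 0.107, edgeR adjusted p 0.0377), 1.34-fold lower. Leaving out any 1 of the 6 libraries kept the direction and ended the call, with edgeR adjusted p from 0.0676 to 0.0948, as did dropping the filter (0.0644) and leaving out shCtrl 3 and shTFAM 3 together (0.0818).

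The 13 mRNAs encoded by mtDNA, which specify subunits of the respiratory chain and ATP synthase, all had negative log2 fold changes, with a median of -0.53. Under quantile normalization MT-ND4, MT-ND4L and MT-CO1 had positive values of 0.089, 0.084 and 0.12. They are abundant rows, at 20060, 16300 and 14090 FPKM in shCtrl. Quantile normalization gives each rank the same value in every library. It can thus remove a fall that the most abundant rows share, and cannot decide whether these mRNAs fell. MT-ND3 fell from 1035 ± 71.7 to 553 ± 115 CPM (SD, n = 3 each; log2 fold change -0.90, SE 0.160, edgeR adjusted p 0.0124). MT-CO3 (-0.70, edgeR adjusted p 0.0378) and MT-CYB (-0.63, edgeR adjusted p 0.0311) also fell, and the remaining 10 did not pass; adjusted over the list alone, the count was again 3. DESeq2 called 5, adding MT-ND2 (DESeq2 adjusted p 0.0412) and MT-ND6 (0.0489). MT-ND6 also passed in edgeR without shCtrl 3 (edgeR adjusted p 0.0268) and with shCtrl 3 and shTFAM 3 left out (0.0393), and MT-ATP8 without shTFAM 2 (0.0223). The list was lower by camera (adjusted p 0.00041, and adjusted p 0.505 with an estimated correlation), and lost its call under quantile normalization (camera adjusted p 0.212, 1 mRNA fallen). It did not pass fry (fry adjusted p 0.109). The calls of MT-CYB and MT-CO3 ended without any 1 library other than shTFAM 2, with edgeR adjusted p from 0.052 to 0.0935 for MT-CYB and from 0.0625 to 0.108 for MT-CO3. Both also ended under quantile normalization (limma adjusted p 0.0708 and 0.214), and that of MT-CO3 without the filter (edgeR adjusted p 0.0521) and with shCtrl 3 and shTFAM 3 left out (0.0846). The list held 4 fallen mRNAs without shTFAM 2, 2 without shCtrl 3 and 1 without each other library. Rows on mtDNA took 12.6 ± 2.19% of counts in shCtrl and 9.09 ± 1.45% in shTFAM (SD, n = 3 each; two-sided exact permutation p 0.2, smallest possible 0.1). Nuclear rows that copy mtDNA genes, with which these reads can be shared, took 0.514 ± 0.0293% and 0.291 ± 0.0705% (SD, n = 3 each; two-sided exact permutation p 0.1, the smallest possible).

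**Figure D1:**
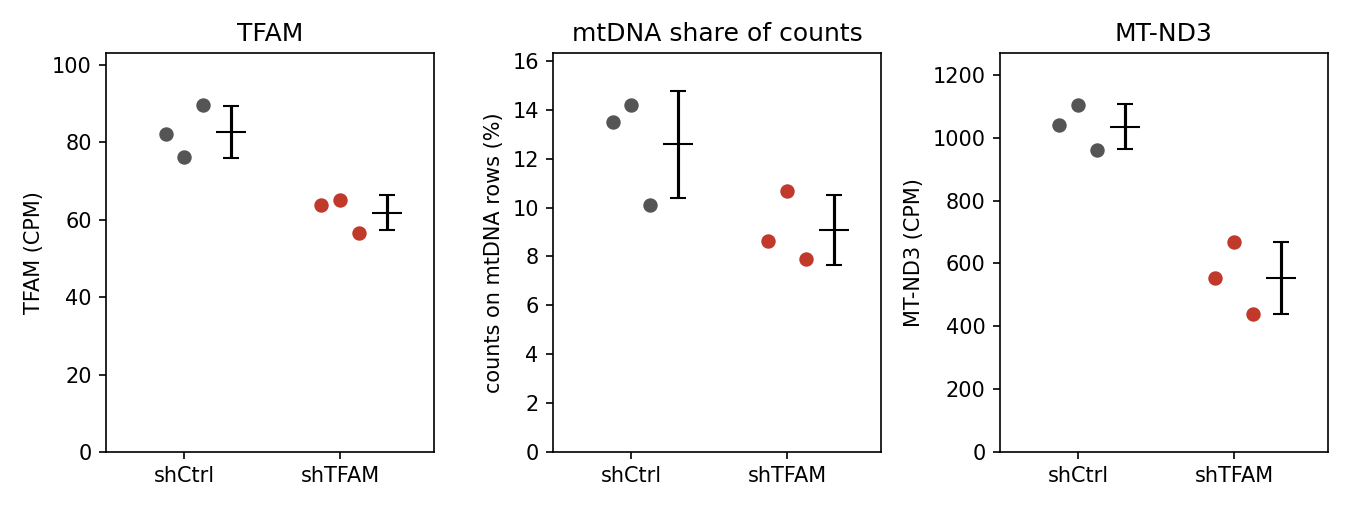
TFAM (CPM), the share of counts on mtDNA rows (%) and MT-ND3 (CPM) in each library; points are libraries, and bars are the mean and SD of 3 libraries per group. TFAM and MT-ND3 do not overlap between the groups, while the mtDNA share of shCtrl 3 (10.1%) lies below that of shTFAM 2 (10.7%).

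Nuclear genes of mitochondrial gene expression were lower in shTFAM. Of 75 mitochondrial ribosomal proteins, 15 fell, 1 rose and 59 did not pass, with the same counts adjusted over the list alone (median log2 fold change -0.26, camera adjusted p 7.17e-06, adjusted p 0.298 with an estimated correlation). MRPL3 fell from 131 to 65.5 CPM, MRPS25 from 205.1 to 101.5 CPM and MRPL2 from 52.6 to 32.0 CPM (-0.72). Of 25 genes of mtDNA maintenance and transcription other than TFAM, 6 fell and none rose, also when adjusted over the list alone (median -0.35, camera adjusted p 0.00041, adjusted p 0.189 with an estimated correlation). Among them were MTERF3 (-0.77), which acts in mitochondrial ribosome assembly, and TOP1MT (-0.59), the mitochondrial topoisomerase. Of 18 mitochondrial chaperones and proteases, 7 fell and none rose (10 fell adjusted over the list alone; median -0.39, camera adjusted p 0.000157, adjusted p 0.189 with an estimated correlation). TIMM44 of the protein import motor fell by 0.61 on the log2 scale and the chaperonin HSPD1 by 0.70, from 1417 ± 226 to 871 ± 117 CPM (SD, n = 3 each). The HSPD1 call ended without shCtrl 2, shTFAM 1 or shTFAM 3, with edgeR adjusted p 0.0591, 0.0626 and 0.0663. Leaving out shCtrl 1, shCtrl 2, shTFAM 1, shTFAM 2 or shTFAM 3 lowered the count of fallen ribosomal proteins to 6, 6, 9, 4 and 4 and of chaperones to 3, 1, 2, 3 and 3; none of the ribosomal proteins rose without any library other than shTFAM 1. The count for mtDNA maintenance went to 3 without shCtrl 1 or shCtrl 2 and 2 without shTFAM 2 or shTFAM 3. Scaling outside mtDNA gave 26 fallen ribosomal proteins and 11 genes of mtDNA maintenance, and quantile normalization gave 23 ribosomal proteins, against 8 with shCtrl 3 and shTFAM 3 left out.

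Nuclear genes of the respiratory chain and of mitochondrial metabolism had calls whose number depended on the scaling, the test and the filter. Among 37 complex I subunits, NDUFS8 fell (-0.46) and 36 did not pass (none adjusted over the list alone). The list did not pass fry (fry adjusted p 0.238) but was lower by camera (adjusted p 0.0279, adjusted p 0.608 with an estimated correlation). That call ended without shCtrl 3 (camera adjusted p 0.191) or without shTFAM 2 (0.13), and that of NDUFS8 without each single library (edgeR adjusted p 0.0523 to 0.0860), without the filter (0.0575) and with shCtrl 3 and shTFAM 3 left out (0.0687). With shCtrl 3 and shTFAM 3 left out, the list did not pass either (camera adjusted p 0.114); scaling outside mtDNA gave 5 lower complex I genes (camera adjusted p 0.00627) and quantile normalization 3 (0.00384). DESeq2 called 4, rows of at least 5 FPKM gave 3, and no filter gave 0. Of 39 subunits of complexes II to V, ATP5F1E rose (0.52) and ATP5F1B (-0.42) and CYC1 (-0.42) fell, the same counts as adjusted over the list alone (camera adjusted p 0.0819). The list passed, as lower, in 9 of 19 alternatives: without shCtrl 1 (camera adjusted p 0.0154), shCtrl 2 (0.0256) or shTFAM 3 (0.0411), and on log2(FPKM + 0.1) (0.0265), log2(FPKM + 1) (0.0283), rows of at least 5 FPKM (0.0291), library totals (0.0273), quantile normalization (0.00227) and scaling outside mtDNA (0.00762). The last 2 gave 8 and 10 lower genes, rows of at least 5 FPKM 6, and DESeq2 4. The calls of ATP5F1B and CYC1 ended without shCtrl 1, shCtrl 2, shTFAM 1 or shTFAM 2 (edgeR adjusted p 0.0676 to 0.0896 and 0.0568 to 0.0816), and that of ATP5F1E without shCtrl 2 (0.0522). In the TCA cycle, 2 of 21 genes rose and 3 fell (3 and 3 adjusted over the list alone), among them citrate synthase CS (-0.45) and SUCLG2 (0.61), and the list did not pass (camera adjusted p 0.573). The CS call ended without shCtrl 2 (edgeR adjusted p 0.0569), and that of SUCLG2 without any library other than shCtrl 3 (0.0575 to 0.0846) or with shCtrl 3 and shTFAM 3 left out (0.0750); over single left-out libraries, 0 to 2 genes of the cycle rose and 0 to 1 fell. In fatty acid oxidation EHHADH fell (-0.58) and 23 of 24 genes did not pass (none adjusted over the list alone; camera adjusted p 0.93, with a negative test direction and mean and a median of 0.0092). Its call ended without any library other than shTFAM 1 (edgeR adjusted p 0.0754 to 0.131), without the filter (0.0791), with edgeR's own filter (0.0534), with no abundance trend (0.0520) and with shCtrl 3 and shTFAM 3 left out (0.107). DESeq2, scaling outside mtDNA, library totals, quantile normalization and both limma pseudocounts gave 3 fallen genes.

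Targets of hypoxia-inducible factors (HIF) showed the widest shift of the lists. Of 24 measured, 21 rose and none fell (23 rose adjusted over the list alone), with a median log2 fold change of 1.75 and positive values in all 24 (camera adjusted p 1.42e-14, adjusted p 0.226 with an estimated correlation). NDRG1 rose from 195 ± 11 to 1483 ± 650 CPM (SD, n = 3 each; log2 fold change 2.93, SE 0.298, edgeR adjusted p 0.00275). The mitophagy receptor BNIP3 rose from 92.6 ± 12.1 to 573 ± 199 CPM (2.63, SE 0.253, edgeR adjusted p 0.00229). ANGPTL4, an inhibitor of lipoprotein lipase, rose from 1.92 ± 0.427 to 45.2 ± 25.9 CPM (4.56, SE 0.446, edgeR adjusted p 0.00239), a log2 fold change of 3.81 with shCtrl 3 and shTFAM 3 left out. Of 23 glycolysis genes, 18 rose and LDHB fell (-0.45); adjusted over the list alone, 19 rose and 1 fell (median 0.95, camera adjusted p 3.44e-09, adjusted p 0.283 with an estimated correlation). Hexokinase HK2 rose from 118 to 813 CPM (2.79), PGK1 from 902 to 3117 CPM (1.79), the lactate exporter SLC16A3 from 195 to 422 CPM (1.11) and PDK1, which restrains pyruvate dehydrogenase and is in both lists, from 55.0 to 174 CPM (1.66). Without shCtrl 2, 12 glycolysis genes rose, and no glycolysis gene fell without any library other than shCtrl 3.

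Genes of the mesenchymal state, matrix proteases and cell adhesion were higher as lists. Of 24 mesenchymal genes, 16 rose and none fell (17 rose adjusted over the list alone; median log2 fold change 0.91, camera adjusted p 2.92e-10, adjusted p 0.189 with an estimated correlation). Fibronectin FN1 rose from 63.9 ± 16.4 to 1583 ± 445 CPM (SD, n = 3 each; log2 fold change 4.63, SE 0.284, edgeR adjusted p 0.000699). The transcription factor SNAI2 rose by 2.60 and the collagen gene COL5A1 by 2.14 on the log2 scale. Of 20 matrix protease and invasion genes, 10 rose and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p 2.72e-05, adjusted p 0.189 with an estimated correlation), among them CTSZ (1.18), MMP2 (1.11) and PLAU (0.85). Of 29 focal adhesion and integrin genes, 15 rose and 1 fell (18 and 1 adjusted over the list alone; camera adjusted p 2.48e-06, adjusted p 0.189 with an estimated correlation). Integrin ITGA1 rose from 47.5 ± 4.51 to 179 ± 3.34 CPM (SD, n = 3 each; 1.92, SE 0.103, edgeR adjusted p 0.000594). Of the protease genes, 6 rose without shCtrl 2, shTFAM 2 or shTFAM 3, and none fell without shCtrl 1, shCtrl 2, shTFAM 2 or shTFAM 3. No adhesion gene fell without shCtrl 1, shTFAM 1, shTFAM 2 or shTFAM 3, and 2 fell without shCtrl 3.

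Cytoskeletal target genes of SRF with its cofactor MRTF, which is released by actin assembly, were also higher. Of 25 measured, 12 rose and none fell (16 rose adjusted over the list alone; median log2 fold change 0.55, camera adjusted p 1.09e-07, adjusted p 0.189 with an estimated correlation). FLNA rose from 1426 to 2678 CPM (0.91), VCL from 372 to 609 CPM (0.71) and CCN1 from 38.7 to 79.8 CPM (1.04). Of 21 YAP and TAZ targets, 12 rose and none fell (13 rose and 2 fell adjusted over the list alone; camera adjusted p 0.000392, adjusted p 0.298 with an estimated correlation), among them FOXF2 (1.78), MYOF (1.03) and F3 (1.58). Of 26 formins and actin nucleators, 6 rose and none fell (7 rose and 1 fell adjusted over the list alone; median 0.20, camera adjusted p 0.0226, adjusted p 0.189 with an estimated correlation). The list lost its call with rows of at least 5 FPKM (camera adjusted p 0.0692), with quantile normalization (0.0699), with scaling outside mtDNA (0.0736, 4 risen and 3 fallen) and with the test on log2(FPKM + 1) (0.0516). Leaving out shCtrl 1, shCtrl 2, shTFAM 1, shTFAM 2 or shTFAM 3 gave 2, 1, 3, 2 and 3 risen nucleators, and without shCtrl 3 another 3 fell. Library totals gave 4 risen and 2 fallen, DESeq2 7 and 1, and leaving out shCtrl 3 and shTFAM 3 gave 4 and 1. Of the YAP and TAZ targets, 1 fell in DESeq2, in the limma tests and under the other scalings. Of the SRF targets 7 rose without shCtrl 2 or shTFAM 1.

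Among the formins that the series title concerns, DIAPH3 (mDia2; ENSG00000139734, chromosome 13, 59665583 to 60163928, hg38) rose from 23.1 ± 0.778 to 37.3 ± 5.02 CPM (SD, n = 3 each; log2 fold change 0.69, SE 0.129, edgeR adjusted p 0.0146). Its call ended without shCtrl 2 (edgeR adjusted p 0.0564) or without shTFAM 2 (0.0527), and with shCtrl 3 and shTFAM 3 left out (0.0667). DIAPH1 (0.22, edgeR adjusted p 0.247) and DIAPH2 (0.17, edgeR adjusted p 0.501) did not pass, and DAAM1 rose from 12.2 to 25.7 CPM (1.07). Of 21 genes of nuclear actin transport and assembly, 6 rose and none fell (9 rose adjusted over the list alone; median 0.28, camera adjusted p 0.00289, adjusted p 0.295 with an estimated correlation). ACTB rose from 2055 ± 191 to 3834 ± 635 CPM (SD, n = 3 each; 0.90, SE 0.147, edgeR adjusted p 0.00956), and ACTG1 stood at 1343 ± 218 and 2120 ± 502 CPM (0.66, edgeR adjusted p 0.0561; 0.0481 without shCtrl 3, 0.0466 with rows of at least 5 FPKM, 0.0128 with shCtrl 3 and shTFAM 3 left out, DESeq2 adjusted p 0.0103, and up to 0.154 over the alternatives). The actin-severing protein gelsolin, GSN, rose from 146 to 271 CPM (0.89). None of 16 genes of malonyl-CoA and fatty acid synthesis passed, over all rows or adjusted over the list alone (camera adjusted p 0.122), against 2630 of 14708 rows overall. In edgeR 2 of the 16 had an unadjusted p under 0.05, and limma on log2(FPKM + 1) called 0. DESeq2 and scaling outside mtDNA each called 1 lower, and with shCtrl 3 and shTFAM 3 left out 1 was higher. SIRT5, which removes malonyl groups from proteins, stood at 22.8 ± 1.85 and 17.1 ± 2.17 CPM (SD, n = 3 each; -0.42, edgeR adjusted p 0.0879), and was called lower by DESeq2 (adjusted p 0.0441) and under scaling outside mtDNA (edgeR adjusted p 0.0487), with adjusted p up to 0.212 over the alternatives. ACACA (-0.24) and FASN (-0.35) did not pass, and MLYCD, malonyl-CoA decarboxylase, was under the filter at 0.234 ± 0.0131 and 0.156 ± 0.00352 FPKM (SD, n = 3 each).

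**Figure D2:**
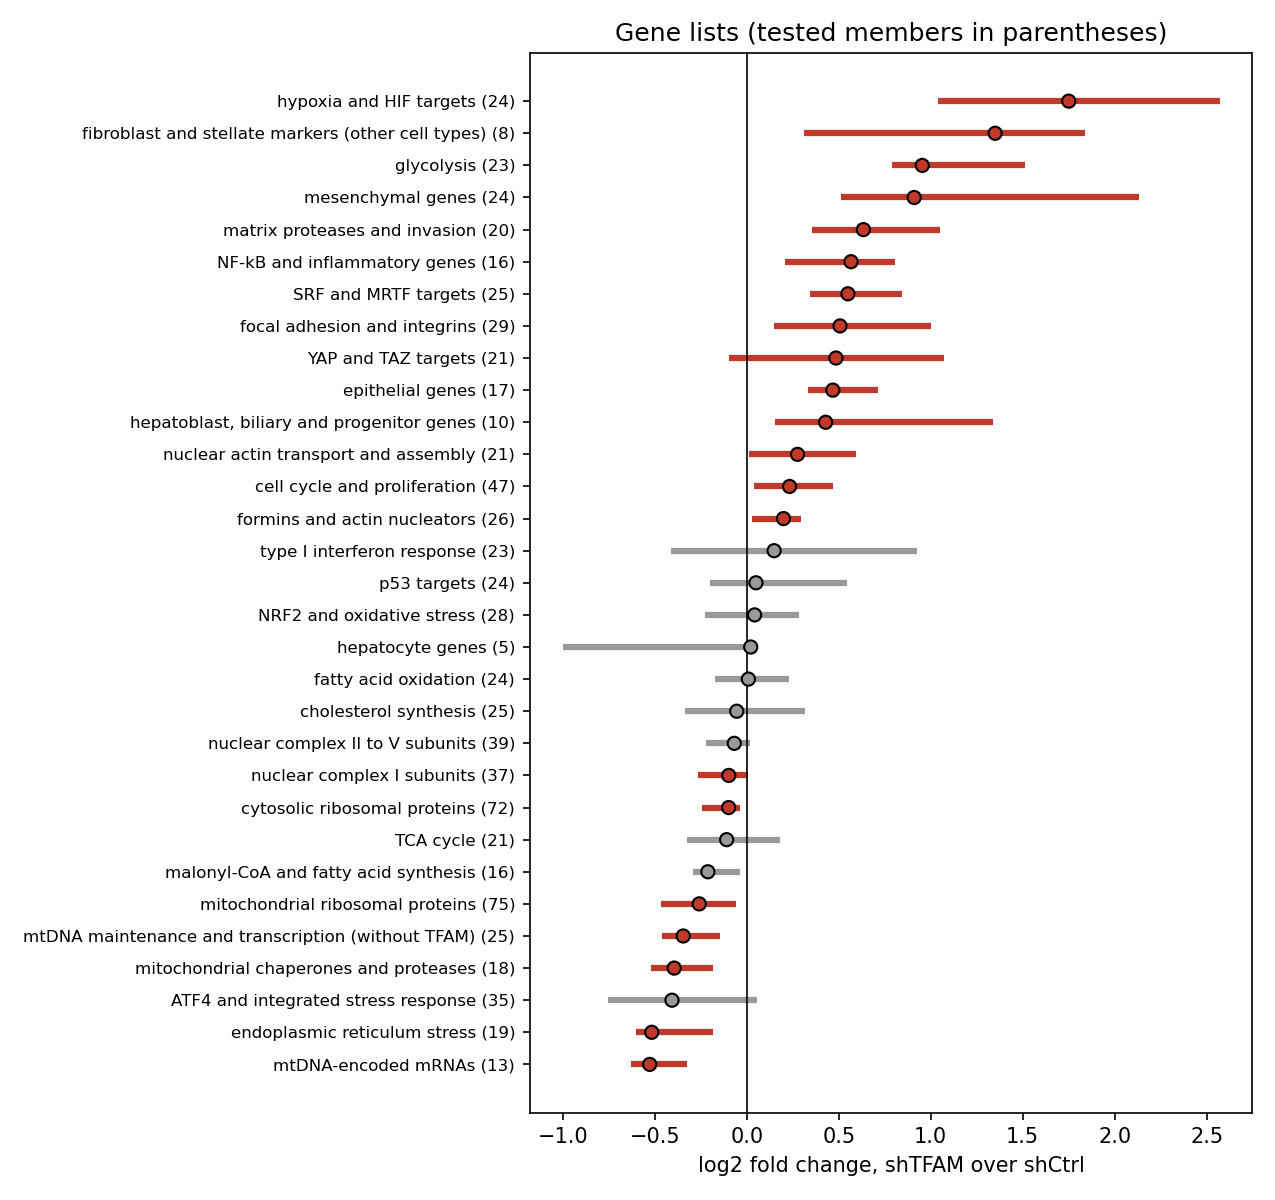
Median (point) and quartiles (bar) of the log2 fold change, shTFAM over shCtrl, of the tested members of 31 gene lists; red marks a camera adjusted p under 0.05 at a preset correlation of 0.01 and grey the rest. The HIF targets have the highest median (1.75) and the mtDNA-encoded mRNAs the lowest (-0.53); none of the lists passed with an estimated correlation.

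Epithelial genes were higher as a list by camera at its preset correlation, with a median log2 fold change of 0.47 and positive values in 14. Of 17 measured, 5 rose and the tight-junction gene OCLN fell (-2.10); adjusted over the list alone, 8 rose and 1 fell (camera adjusted p 0.00374, adjusted p 0.189 with an estimated correlation). CLDN4 (1.66) and SPINT1 (1.27) were among those that rose. Only 5 of 40 hepatocyte genes passed the filter; C4BPA rose (2.91), and CEBPA (27.4 to 13.7 CPM) and VTN (-1.85) fell, with the same counts adjusted over the list alone (camera adjusted p 0.584, with a negative test direction and a median and mean of 0.022 and 0.023). The VTN call ended without shCtrl 1, shCtrl 2, shTFAM 1 or shTFAM 2 (edgeR adjusted p 0.0516 to 0.0597). Of 10 hepatoblast, biliary and progenitor genes, 3 rose and IGF2BP1 fell (5 and 2 adjusted over the list alone), with THY1 (1.54), the imprinted RNA H19 (2.75) and CD24 (1.79) higher (camera adjusted p 0.0212, adjusted p 0.226 with an estimated correlation). That call ended without the filter (camera adjusted p 0.0781) and with rows of at least 5 FPKM (0.0855), and IGF2BP1 lost its call without shCtrl 1, shTFAM 1 or shTFAM 2 (edgeR adjusted p 0.0660 to 0.0750). Without shCtrl 1 or shCtrl 2, 3 and 2 epithelial genes rose. Markers of other cell types moved with the groups beside the mesenchymal genes. Of 8 fibroblast and stellate markers, 4 rose and none fell (6 rose adjusted over the list alone; camera adjusted p 0.000149, adjusted p 0.189 with an estimated correlation): DCN from 3.06 to 23.6 CPM, MFAP5 from 16.8 to 81.4, PDGFRB from 15.5 to 49.9 and THY1 from 49.0 to 143 CPM. All 3 measured leukocyte markers rose, also when adjusted over the list alone, among them CD68 from 13.8 to 37.0 CPM and CSF1R from 25.6 to 49.8 CPM. The CSF1R call ended without any 1 shCtrl library (edgeR adjusted p 0.0623 to 0.0630). The 1 endothelial marker measured, EGFL7, did not pass (-0.075; 0.061 without shCtrl 1 and 0.12 without shTFAM 2), also when adjusted over the list alone. These last lists had under 5 members tested and no list test. Without the filter, the leukocyte list of 8 genes was higher (camera adjusted p 0.0194; 0.0851 for 6 genes under edgeR's own filter) and the endothelial list of 9 did not pass (0.145).

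Of 47 cell cycle genes, 11 rose and 1 fell (14 and 1 adjusted over the list alone; median log2 fold change 0.23, camera adjusted p 0.00017, adjusted p 0.446 with an estimated correlation). MKI67 rose from 356 to 869 CPM (1.29) and the actin-binding cytokinesis protein ANLN from 251 to 748 CPM (1.57). Of 16 NF-kB and inflammatory genes, 6 rose and none fell (8 rose adjusted over the list alone; camera adjusted p 0.0005, adjusted p 0.407 with an estimated correlation), with TNFAIP3 at 2.39 and 11.6 CPM and C3 at 771 and 1270 CPM. Of 72 cytosolic ribosomal proteins, 5 fell and RPS21 rose (1 fell adjusted over the list alone; median -0.10, camera adjusted p 0.00109, adjusted p 0.608 with an estimated correlation), RPS15 by the most (-0.63). This list did not pass fry (fry adjusted p 0.125). Interferon genes went both ways: the RNA sensor IFIH1 fell from 22.6 to 3.47 CPM (-2.70), OAS3 rose by 1.87 on the log2 scale, and of 23 genes 3 rose and 3 fell (4 and 6 adjusted over the list alone; camera adjusted p 0.635). Of 28 NRF2 genes 3 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p 0.573), with AKR1C3 (2.63) higher and GCLC (-0.59) lower; the GCLC call ended without shCtrl 2 (edgeR adjusted p 0.0513). Of 24 p53 targets 3 rose and 1 fell, also when adjusted over the list alone (camera adjusted p 0.605), with PERP (0.61) higher. Of 25 cholesterol synthesis genes 2 rose and SQLE fell (none adjusted over the list alone; camera adjusted p 0.94, with a negative test direction and median and a mean of 0.021). SQLE lost its call without each single library (edgeR adjusted p 0.05 to 0.0855), without the filter (0.0544) and with shCtrl 3 and shTFAM 3 left out (0.0746). No cholesterol gene rose in the limma tests or under scaling outside mtDNA or library totals, and 5 rose with shCtrl 3 and shTFAM 3 left out. Leaving out shCtrl 1, shCtrl 2, shTFAM 2 or shTFAM 3 gave 5, 6, 5 and 7 risen cell cycle genes and 2, 3, 2 and 2 risen NF-kB genes. No cytosolic ribosomal protein rose without any library other than shTFAM 2, and 1 to 6 fell. Fallen cytosolic ribosomal proteins numbered 17 under scaling outside mtDNA and 15 under quantile normalization. They numbered 12 on log2(FPKM + 0.1), log2(FPKM + 1) and library totals, 11 with rows of at least 5 FPKM, 10 in DESeq2 and 3 without the filter. Scaling outside mtDNA also gave 7 fallen interferon genes, and 3 risen NF-kB genes, against 2 without the filter. DESeq2 called 6 interferon genes higher and 6 lower, 5 NRF2 genes higher and 5 p53 targets higher, and limma on log2(FPKM + 1) called 1 NRF2 gene higher. Over single left-out libraries, risen and fallen genes numbered 2 to 5 and 1 to 3 for interferon, 1 to 3 and 1 to 3 for NRF2, and 1 to 2 and 0 for p53.

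The call of the endoplasmic reticulum stress list depended on the control libraries. Of 19 measured, EDEM1 rose (0.51) and CALR fell (-0.62), neither adjusted over the list alone, while the list was lower by camera (median log2 fold change -0.52, adjusted p 0.0158, adjusted p 0.687 with an estimated correlation). By fry it did not pass (fry adjusted p 0.373). The list lost its call without shCtrl 1 (camera adjusted p 0.0779) or shCtrl 2 (0.0819), and without shCtrl 3 it had 10 genes lower and a camera adjusted p of 5.15e-06. The EDEM1 call ended without any library other than shCtrl 1 (edgeR adjusted p 0.0535 to 0.104) and in 12 of 20 alternatives in all. These included no filter (0.0586), scaling outside mtDNA (0.1), library totals (0.0632), shCtrl 3 and shTFAM 3 left out (0.0656) and, with limma, quantile normalization (limma adjusted p 0.0670), log2(FPKM + 0.1) (0.0712) and log2(FPKM + 1) (0.0685). The CALR call ended without any library other than shCtrl 3 (edgeR adjusted p 0.0765 to 0.12) and without the filter (0.0581). DESeq2 called 1 gene higher and 4 lower, scaling outside mtDNA 3 lower, and leaving out shCtrl 3 and shTFAM 3 gave 7 lower. The chaperone HSPA5, chosen after its values were seen, stood at 3591, 3752 and 950 CPM in shCtrl and at 1721, 863 and 684 CPM in shTFAM (edgeR adjusted p 0.133). Of 35 genes of the integrated stress response, 3 rose and MARS1 fell (2 and 1 adjusted over the list alone; camera adjusted p 0.14). DESeq2 called 4 higher and 7 lower, and scaling outside mtDNA gave 2 and 4. This list passed without shCtrl 3 (camera adjusted p 0.000643, 9 genes lower) or without shTFAM 1 (0.0272), and with shCtrl 3 and shTFAM 3 left out (0.00159, 6 lower), and MARS1 lost its call without shCtrl 1, shCtrl 2, shTFAM 2 or shTFAM 3 (edgeR adjusted p 0.0520 to 0.0645). Of the risen genes, the amino acid transporter SLC7A5 (0.46) lost its call in 14 of 20 alternatives (adjusted p up to 0.111), each single left-out library among them, and CEBPB (1.05) without shTFAM 3 (edgeR adjusted p 0.0674).

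Among the largest changes outside these lists, SNRPN, an imprinted gene of chromosome 15, had 8, 4 and 8 counts in shCtrl and 1891, 1444 and 1727 in shTFAM (log2 fold change 7.93, SE 0.309, edgeR adjusted p 0.000185). BARX1 (4.66), CASP14 (4.25), EDN2 (4.07) and C4BPB (3.63) also rose, as did IGFBP3 (4.48), which belongs to the YAP and TAZ list. Without shTFAM 3 the log2 fold change was 3.48 for CASP14 and 3.87 for IGFBP3, and without shCtrl 1 it was 5.31 for BARX1. With shCtrl 3 and shTFAM 3 left out it was 3.88 for BARX1 and 3.24 for EDN2; each of these kept its call. UGT1A7 (3.96) rose as well, though it shares exons with other UGT1A rows, and SNORD36B, which lies inside RPL7A, had 1 count in each shCtrl library and 32, 37 and 42 counts in shTFAM. The largest falls were in C1GALT1C1, a chaperone of O-glycosylation (20.2 ± 5.00 to 3.09 ± 0.641 CPM; SD, n = 3 each; -2.71, edgeR adjusted p 0.00225), and ACTL8 (-2.31). TXNIP, which restrains glucose uptake, fell from 202 to 43.8 CPM (-2.20) and the glucose-sensing factor MLXIPL from 28.3 to 9.91 CPM (-1.52). AGT (-1.99), PRSS56 (-1.95), TMC5 (-1.81) and PRRT3-AS1 (-1.49) fell too, the last an antisense row whose reads may not be told from its partner's. The mitochondrial tRNA rows MT-TM (-2.19), MT-TQ (-2.19) and MT-TS1 (-1.59) and the mtDNA-like nuclear row MTRNR2L12 (-1.54) were also lower, at group means of 0.803 to 12.1 CPM, and are short features or can share reads. Calls ended for MT-TS1 without shCtrl 2 (edgeR adjusted p 0.0509), for MLXIPL without shCtrl 2, shTFAM 2 or shTFAM 3 (0.0516 to 0.0576) and for MTRNR2L12 without any library other than shCtrl 3 (0.0870 to 0.125), without the filter (0.0610) and in the 3 limma tests (limma adjusted p 0.0522 to 0.0621).

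**Figure D3:**
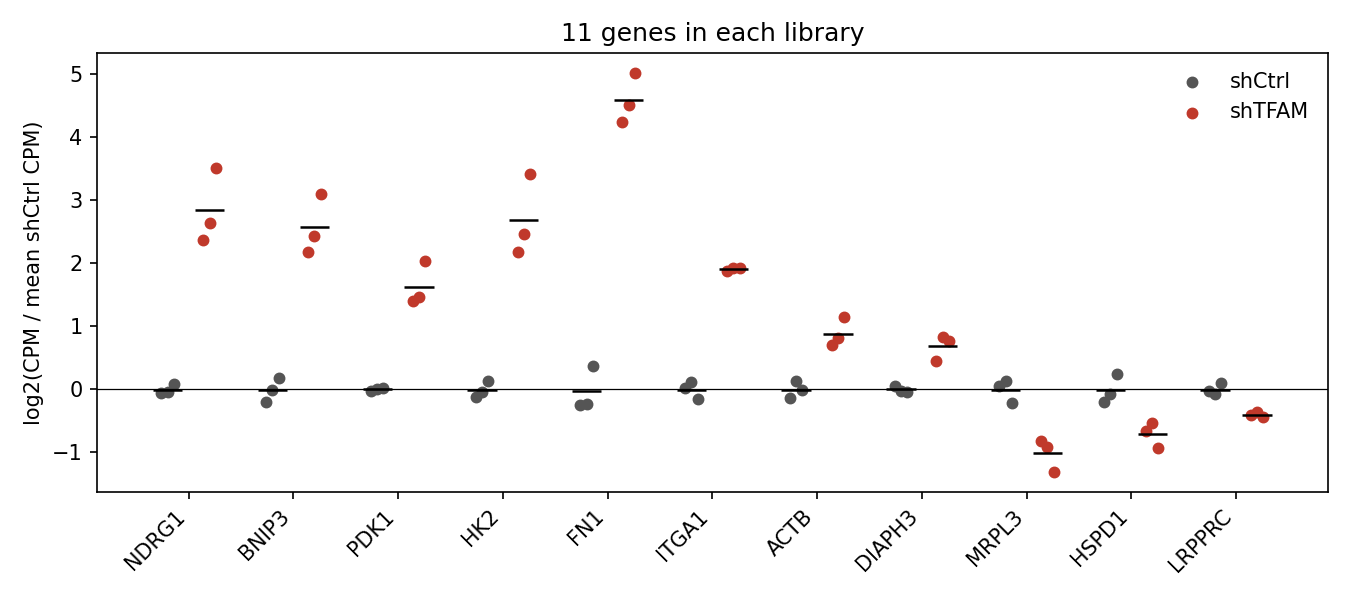
CPM of 11 genes in each library, as log2 of the ratio to the mean of the 3 shCtrl libraries; points are libraries and horizontal lines are means of the log2 ratios. All 11 genes separate the groups, and shTFAM 3 is the highest library for NDRG1, BNIP3, PDK1, HK2, FN1, ITGA1 and ACTB.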

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

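DESeq2, library totals, edgeR's own filter and the joint removal of shCtrl 3 and shTFAM 3 were chosen after the data were seen; so was edgeR as the test, once counts were found, with the limma test fixed before kept as an alternative. TFAM stayed lower in all 20 alternatives (log2 fold change -0.55 to -0.30). Its call ended without the filter (-0.42, adjusted p 0.0644), with shCtrl 3 and shTFAM 3 left out (-0.30, adjusted p 0.0818) and without each single library (-0.48 to -0.36); the cause was not tested. The count of 2630 genes stayed within 1.5 times under the other tests, filters and scalings, from 1766 to 3850, and 56.2 to 99.7% of the 2630 were called again. Leaving out 1 library gave 1148 to 2065 genes, 843 to 1332 higher and 305 to 733 lower, and leaving out shCtrl 3 and shTFAM 3 together gave 2003, more than 5 of the 6 single removals, so the counts do not follow the number of samples alone; the cause was not tested. Stricter thresholds gave fewer by construction: 910 genes (643 higher, 267 lower) with an absolute log2 fold change of at least 1, and 698 (559 and 139) at adjusted p under 0.01. Rows of at least 5 FPKM gave 1020 higher, with fewer genes tested. Scaling outside mtDNA gave 1771 lower, and it left out the TMM factors as well as the mtDNA counts. Library totals, which left out the TMM factors only, gave 1272 lower. DESeq2 gave 1677 lower, and the cause of that was not tested. The 21 lists became 0 with an estimated correlation, and 19 to 22 otherwise. The 14 lists called higher and the 7 called lower kept their direction in all alternatives that tested them, 19 each and 18 for fibroblast markers, too few with rows of at least 5 FPKM; DESeq2 ran no lists. Of 2961 comparisons of 150 results over named genes, 2671 kept direction and side of the threshold, 272 lost and 12 gained the call, and 6 reversed: MT-ND4 (0.089), MT-ND4L (0.084) and MT-CO1 (0.12) under quantile normalization, EGFL7 without shCtrl 1 (0.061) and without shTFAM 2 (0.12; -0.34 to 0.12 over single libraries), and DIAPH2 with shCtrl 3 and shTFAM 3 left out (-0.026). None of these had a call. Quantile normalization can remove a fall that the most abundant rows share, and how far it did so here was not tested. The cause of the other reversals was not tested either. The pseudocount of 1 FPKM understates folds of low genes, such as SNRPN (log2 fold change 3.15 on log2(FPKM + 1), 7.93 in edgeR). No paired analysis was possible because the labels give no shared replicate numbers. Depth limits rows near the floor of 0.0491 to 0.0693 CPM, such as the 1 count of SNORD36B in each shCtrl library.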

Other observations

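In this part, the tests of enriched terms and of chromosome windows were chosen after the data were seen, as were the split, scaling, single-library, culture, adjacent-window and nuclear-copy tests. Genes annotated to ribosome biogenesis and rRNA processing were lower in shTFAM by camera at its preset correlation. These terms share genes, among them NOP56, BOP1 and EMG1, so they are not separate results. Of 102 genes annotated to ribosome biogenesis, 34 fell and 3 rose (median log2 fold change -0.45, camera adjusted p 1.01e-09, adjusted p 0.42 with an estimated correlation), and of 162 rRNA processing genes 43 fell and 1 rose (-0.34, adjusted p 7.9e-10, adjusted p 0.417 with an estimated correlation). NOP56, a core protein of box C/D snoRNPs, fell from 189 to 111 CPM (-0.77), BOP1 from 121 to 67.3 CPM (-0.85) and EMG1 from 127 to 73.2 CPM (-0.79). Basement membrane genes were higher, with 32 of 56 risen and 2 fallen (median 0.73, camera adjusted p 5.23e-08, adjusted p 0.331 with an estimated correlation). NID1 rose from 4.95 to 52.6 CPM (3.41) and COL4A2 from 207 to 421 CPM (1.03). Of 24 genes of semaphorin and plexin signalling, 14 rose and none fell (median 0.59, camera adjusted p 9.58e-06, adjusted p 0.34 with an estimated correlation), among them PLXND1, from 121 to 416 CPM (1.78). Of 3012 terms tested, 739 passed and 0 passed with an estimated correlation.

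The hepatocyte genes ALB, APOA1 and TTR, and AFP of the hepatoblast list, were listed at 0 counts in all 6 libraries. The urea cycle genes CPS1 (1477 ± 141 and 1512 ± 84.9 CPM) and ASS1 (702 ± 111 and 713 ± 75.7 CPM; SD, n = 3 each) were abundant in both groups. Beside SNRPN on chromosome 15, the neighbouring row SNHG14 had 35, 4 and 7 counts in shCtrl and 1423, 1466 and 1598 in shTFAM. CDKN1C, which like H19 is an imprinted gene of chromosome 11, rose from 21.1 ± 3.43 to 64.4 ± 19.6 CPM (SD, n = 3 each; log2 fold change 1.61, edgeR adjusted p 0.00634). Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave as many as 2630 genes, and the highest of the others gave 2. For gene lists, 1 split gave as many as the real 21, but each of the others also gave lists, from 6 to 15. The list calls at the preset correlation therefore set the real grouping apart far less than the gene calls did. With 10 splits no share under 0.05 is possible.

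The rise of HIF targets was weighed against technical explanations. The values argue against scaling, with a lowest median log2 fold change of 1.5 over 4 scalings, and without shTFAM 3, the library with the highest mean of the list, 18 of the 24 targets were still called. After a smooth trend on GC content and transcript length was removed, the median was 1.69 and the lower quartile 1.05. The gap between the lowest shTFAM and the highest shCtrl library was 1.39 log2 units, and the oxygen or density of the cultures, which the labels do not record, cannot be told apart from the knockdown because both would move with the groups. TFAM knockdown, a differing culture state, or a difference between the lines that arose before or after transduction may each account for it.

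Neighbouring genes shifted together in some regions. Over 260 windows of 10 Mb with at least 15 tested genes, the SD of window medians was 0.15, against at most 0.108 in 1000 shuffles of the genes. Of these, 10 had medians of at least 0.3 and 8 of at most -0.3, all 18 with the same sign in all 3 shTFAM libraries. That agreement follows largely from choosing windows by the group median and comparing each library with the same shCtrl mean. Windows with small medians could have it too, such as chromosome 17 from 80 to 90 Mb (0.0085). The highest medians were on chromosome 10 from 130 to 140 Mb (0.61) and chromosome 21 from 40 to 50 Mb (0.57). Others lay on chromosome 20 from 50 to 70 Mb (0.51 and 0.40) and chromosome 10 from 120 to 130 Mb (0.35). Chromosome 15 had adjacent high windows from 20 to 60 Mb (0.30, 0.32, 0.35 and 0.46). Chromosome 8 had 3 low windows, at 100 to 110, 120 to 130 and 140 to 150 Mb (-0.35, -0.32 and -0.40), and 1 high window at 20 to 30 Mb (0.37). The other 5 low windows lay on chromosomes 2 (160 to 170 Mb, -0.33), 6 (110 to 120 Mb, -0.33), 12 (80 to 90 Mb, -0.33), 19 (20 to 30 Mb, -0.31) and 21 (0 to 10 Mb, -0.32). The values argue against a GC and length trend, since 92.4% of the SD stayed after its removal. Within-group contrasts reached a relative spread of 0.288 against 0.321 between groups, so clustering that any difference shows cannot be told apart. Genes left out of the choice of windows kept 59.7% of the shift, under the bound set before, and had the same sign in 26 of 27 windows. Choosing windows by the size of their median can itself lower the share kept. A candidate explanation is copy-number differences of large segments between the lines, which stays open: adjacent windows correlated at r = 0.287 over 216 pairs across windows, which are not independent replicates, above the highest of 1000 shuffles (0.22) but under the 0.4 set for it.

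The lower mitochondrial genes were tested against place on shifted segments and, for the mtDNA-encoded mRNAs, against reads moved to nuclear copies. Several of them, such as MTERF3 and TOP1MT, lie on chromosome 8, but less the median of the other genes of each window, mitochondrial ribosomal proteins kept 90.4% of their median, so place on shifted segments may account for little of it. The list of mtDNA maintenance, which holds MTERF3 and TOP1MT, kept 78.0%, under the bound set before for the ribosomal proteins. The chaperones kept 82.9%. TOP1MT (-0.59) lies in the window of chromosome 8 from 140 to 150 Mb, with a median of -0.40. MTERF3 (-0.77) lies in that from 90 to 100 Mb, with a median of -0.17. For mtDNA-encoded mRNAs, reads moved to nuclear copies would raise those copies, and their share of counts changed by -0.223 percentage points instead, lower in every shTFAM library than in any shCtrl library.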
